A study of Arabidopsis thaliana with 24 samples.

How the data were processed

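RNA from Arabidopsis thaliana leaves of 4 genotypes was measured on two-colour Agilent expression arrays. The genotypes were wild type Col-0 (WT) and the mutants med14, med16 and npr1. MED14 and MED16 are subunits of Mediator, the complex that links transcription factors to RNA polymerase, and NPR1 is a transcriptional coactivator in salicylic acid signalling. Leaves were sampled at 0 h and 4 h after infiltration of Pseudomonas syringae pv. tomato DC3000 carrying avrRpt2, an effector that makes this strain avirulent on Col-0. The 8 groups of genotype and time held 3 samples each, 24 in all. Each sample pooled leaves from 8 plants, and the labels call the replicates biological.

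Per the labels, 2 samples of opposite dye shared each of the 12 arrays. WT and med16 samples shared arrays, as did med14 and npr1 samples, always of the same time and replicate number. In replicate 1 the WT and med14 samples carried Cy3 and the others Cy5, and in replicates 2 and 3 the dyes were exchanged. For the npr1 samples at 0 h the labels disagree: title and source name give 0 h and 1 characteristic gives 4 h. The title was used.

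The deposited values are one number per probe and sample on a log2 scale. The log base is not stated and was inferred from the range, since on a natural log scale the brightest values would exceed what a scanner records. All 24 columns share nearly one distribution, with medians of 7.81 to 7.82 (log2), so the values had been normalized between all channels before they were deposited. Per the submitters' processing notes, Agilent Feature Extraction 10.1.1.1 and R 2.15.2 were used. The background correction, the normalization function and any filters are not given in the sources used here. The table held 33200 rows, of which 57 were array controls. The controls were left out of all tests, which left 33143 probes, each with 1 row.

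The files do not pair the probes with genes, and 0 probe identifiers were found in the gene table used here. Each probe was therefore tested on its own and is printed by its identifier, and a gene represented by several probes is counted more than once. The levels of MED14, MED16 and NPR1 in the mutants, which would check the labels, could not be given. The defence, hormone, cold, iron, photosynthesis, clock and cell type lists fixed beforehand could not be tested, nor could the alternatives that differ in how probes of one gene are combined.

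A background limit was set for each sample at the highest of 14 control rows that lack a target. It lay between 6.40 and 6.92 (log2), and 20033 to 24961 probes per sample (60.4% to 75.3%) were above it. A probe at or under the limit in all 3 samples of a group has only a bound there. For such a probe the fold is given as at least the bright group's mean over the mean of, per sample, the higher of the limit and the probe's own signal. The number of arrays limits the precision, and no scanner flags for saturation were used here.

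Differences were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3. One model was fitted to all 24 samples, with a mean for each of the 8 groups and a term for dye. The array was a random block, with a consensus correlation of 0.460 estimated by duplicateCorrelation. Adjusted p-values are from this limma model with Benjamini-Hochberg adjustment over the 33143 probes of a comparison. A probe was called at an adjusted p under 0.05, with counts of at least 2-fold changes given beside. Standard errors (SE) of differences come from the model and SDs are over the 3 samples of a group. The comparisons were 4 h against 0 h in each genotype, each mutant against WT at each time, the response (4 h minus 0 h) of each mutant minus that of WT, and the response of med14 minus that of med16. The shared arrays made the med16 comparisons with WT more precise. The median SE at one time was 0.0801 (log2) for med16, 0.107 for med14 and 0.108 for npr1, so counts of calls are not comparable between mutants.

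The size of the response was summarised over probes called in the mean response of the 4 genotypes and changed at least 2-fold, which avoids choosing probes on WT alone. Mean responses per replicate number were compared between genotypes by two-sided exact permutation tests of 3 values against 3, whose smallest p is 0.1. The replicate numbers were not taken to pair the samples, so joining 4 h with 0 h by number is arbitrary. The SDs over replicate numbers and these p depend on it. The tests also ignore that WT and med16 samples shared arrays. Overlaps of calls between comparisons that share the WT samples are given with the count that independent lists would share and with the correlation in 20 simulations of unchanged groups. The fit was tested on simulated data, with 200 of the 33143 probes changed. At a change of 1 (log2) it recovered 90% for the WT response, 80% for the med14, 92% for the med16 and 81% for the npr1 response minus that of WT. At a change of 0.5 it recovered 54%, 18%, 59% and 21% in the same order. False calls were 9.43%, 3.92%, 6.21% and 4.67% of the calls, and ranged from 0.662% to 9.43% over the 14 comparisons, with 1 simulation each. Most real comparisons called a far larger share of probes (42.7% for the WT response). The adjustment depends on that share, so these rates need not hold for the real data.

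The probes named in the text follow a rule fixed before the data were examined. They are those with the highest and lowest log2 differences among called probes whose 3 samples of one group all lie beyond the 3 of the other, or among all called probes for differences between responses. Without gene names the number was reduced to 2 in each direction per comparison.

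Replicates of one group correlated with a median r of 0.993 over probes (lowest 0.989), and no 2 samples shared over 0.250% of values within 1e-06. Deviations from the group means correlated in samples of the same array (median r 0.591 in 12 pairs), which the array block takes into account. Alternatives covered the dye term, the array block, a replicate block, fits to the compared groups alone, repeated normalization, median centring, dim probes, the fold threshold, eBayes with trend and robust, the npr1 samples at 0 h, and each replicate left out in turn. Scaling to 10 spike-in control rows, leaving out probes below the median signal, and choosing responsive probes from the genotypes not compared were added after seeing the data.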

Results

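Transcript levels were measured with 33143 array probes in leaves of WT, med14, med16 and npr1 plants at 0 h and 4 h after inoculation with the avirulent bacterium, in 3 samples per group. The signal was above background for 60.4% to 75.3% of the probes per sample. Time separated the samples most. The first principal component held 70.7% of the variance and lay between -89.9 and -63.5 for all 12 samples of 0 h and between 54.8 and 117.8 for all 12 samples of 4 h. The npr1 samples at 0 h, whose labels disagree on the time, lay between -78.5 and -74.9, within the range of the other samples of 0 h. The second component (9.03%) placed WT and npr1 above 0, at 11.4 to 42.3, and both Mediator mutants below 0, at -43.5 to -11.8. No mock-inoculated samples were part of the design, so each difference between 4 h and 0 h includes infiltration and time of day. Each array held samples of a single time. A batch of labelling or hybridization that follows time would therefore be included as well.

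The first comparison asked how WT leaves responded within 4 h. The largest rise was at probe A_84_P14560, from 6.62 ± 0.124 (SD, n = 3) to 15.06 ± 0.438 (log2), a difference of 8.44 ± 0.196 (SE; adjusted p = 2.08e-15, limma). Its mean at 0 h lay among the background limits of these samples (6.48 to 6.64), so the size is uncertain. A_84_P113182 rose by 7.81 ± 0.300, a 224-fold change (adjusted p = 2.02e-13, limma). A_84_P19997 fell by 4.69 ± 0.379 (adjusted p = 4.16e-09, limma) and A_84_P11569 fell by 4.45 ± 0.461 (adjusted p = 1.3e-07, limma). In all, 5451 probes rose and 8693 fell, together 42.7% of the probes tested. Of these, 2325 rose and 1971 fell at least 2-fold, so that rises were the majority of the larger changes. The share of rises also depended on the scaling. It was 38.5% with the deposited normalization and 69.2% (6530 up, 2905 down) after scaling to the spike-in controls, which moved the median difference of all probes from -0.05 to 0.26.

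The same comparison in med14 gave 5914 probes up and 8620 down, and at least 2-fold 2359 up and 1871 down, where rises were the majority. A_84_P812152 rose by 7.99 ± 0.414 (SE, n = 3 per group; adjusted p = 1.37e-11, limma) and A_84_P10609 by 7.50 ± 0.591 (adjusted p = 3.46e-09, limma). The deepest falls were again at A_84_P11569, with -4.78 ± 0.461 (adjusted p = 5.42e-08, limma), and A_84_P19997, with -4.60 ± 0.379 (adjusted p = 6.29e-09, limma). The probe with the largest rise in WT, A_84_P14560, was not above background in med14 at 0 h and reached 10.09 ± 0.427 (SD) at 4 h, where it was lower than in WT with a difference of -4.97 ± 0.196 (adjusted p = 4.92e-12, limma). With spike-in scaling the share of rises in med14 moved from 40.7% to 61.9%, the number of calls to 9090 and the median difference from -0.04 to 0.17.

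In med16, 7105 probes rose and 9534 fell, and 7092 changed at least 2-fold (3374 up, 3718 down), against 4296 in WT. A_84_P812152 rose by 9.38 ± 0.414 (adjusted p = 3.7e-13, limma), from 7.79 ± 1.08 (SD, n = 3) to 17.17 ± 0.137, and A_84_P10609 rose by 8.99 ± 0.591 (adjusted p = 9.79e-11, limma). A_84_P19997 fell by 5.65 ± 0.379 (adjusted p = 1.31e-10, limma) and A_84_P16974 fell by 5.56 ± 0.330 (adjusted p = 2.27e-11, limma). The share of rises was 42.7%, and 57.2% with spike-in scaling, where the median difference was 0.19 in place of -0.04.

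In npr1, 4797 probes rose and 8209 fell. At least 2-fold rises were the majority, with 2027 up and 1325 down. A_84_P113182 rose by 7.75 ± 0.300 (adjusted p = 3.95e-13, limma), which differed from its WT response by -0.05 ± 0.424 (adjusted p = 0.983, limma). A_84_P18989 was not above background in any npr1 sample at 0 h and was at least 164-fold higher at 4 h, at 13.96 ± 0.145 (SD, n = 3; adjusted p = 8.26e-14, limma). A_84_P19997 fell by 4.19 ± 0.379 (adjusted p = 2.89e-08, limma) and A_84_P175171 fell by 3.75 ± 0.159 (adjusted p = 1.17e-12, limma). The share of rises moved from 36.9% to 65.5%, the number of calls to 7128 and the median difference from -0.05 to 0.18 with spike-in scaling.

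**Figure D1:**
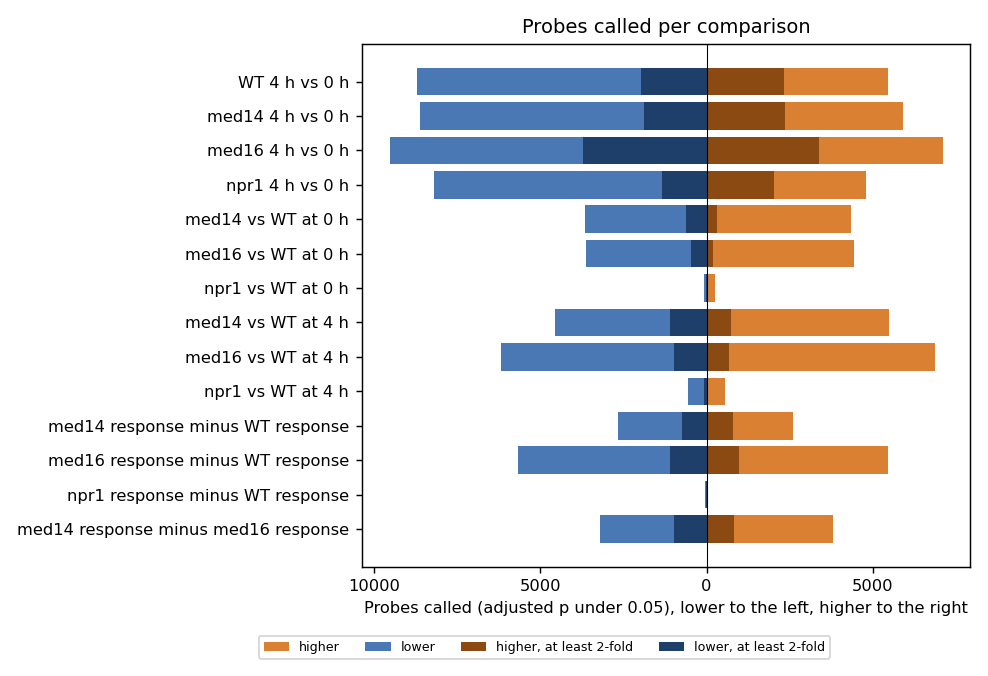
Number of probes called in each of the 14 comparisons (adjusted p under 0.05, limma), with higher probes to the right of 0 and lower probes to the left, and the part that changed at least 2-fold drawn in a darker shade over each bar. The bars for the npr1 mutant against WT stand for 343 probes at 0 h and 1114 at 4 h. Bars are not comparable between mutants, as the median SE against WT was 0.0801 (log2) for med16, 0.107 for med14 and 0.108 for npr1.

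Whether the genotypes differed in the size of the response was examined over 2463 probes that rose and 2111 that fell in the mean of all genotypes. The median rise was 1.86 in WT, 1.63 in med14, 2.35 in med16 and 1.62 in npr1 (log2). The median fall was -1.25 in WT, -1.24 in med14, -1.90 in med16 and -1.05 in npr1. Averaged over risen probes, the response in med16 was 2.73 (SD 0.10 over 3 replicate numbers), larger by 0.53 than the WT mean (SD 0.159). Over fallen probes it was -2.02 ± 0.0776 in med16 and -1.38 ± 0.0584 in WT. The median difference of med16 from WT was -0.17 at 0 h and 0.30 at 4 h over risen probes, and 0.12 at 0 h and -0.53 at 4 h over fallen probes. The differences in mean response separated all replicates in both probe sets, and the exact permutation p was 0.1, the smallest that 3 against 3 allow. This p does not take the arrays shared by WT and med16 into account.

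Probe by probe, 1338 of the 2463 risen probes had a larger response in med16 than in WT by the interaction test and 240 a smaller one. Among fallen probes the fall was larger in med16 at 1490 and smaller at 123. In med14 the risen probes were divided, with 369 larger and 772 smaller responses (median difference -0.30, exact permutation p = 0.2), and the fallen probes showed 274 larger and 319 smaller ones (median difference 0.00, exact permutation p = 0.5). In npr1, limma called 0 responses larger (32 risen and 25 fallen at an unadjusted p under 0.05), while 34 risen and 21 fallen probes had a smaller one (median differences -0.20 and 0.20, exact permutation p = 0.2 and 0.1). Without the fold threshold the median differences were smaller, at -0.023 for med14 and 0.32 for med16 over risen probes, and -0.19 for med16 and 0.076 for npr1 over fallen probes.

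**Figure D2:**
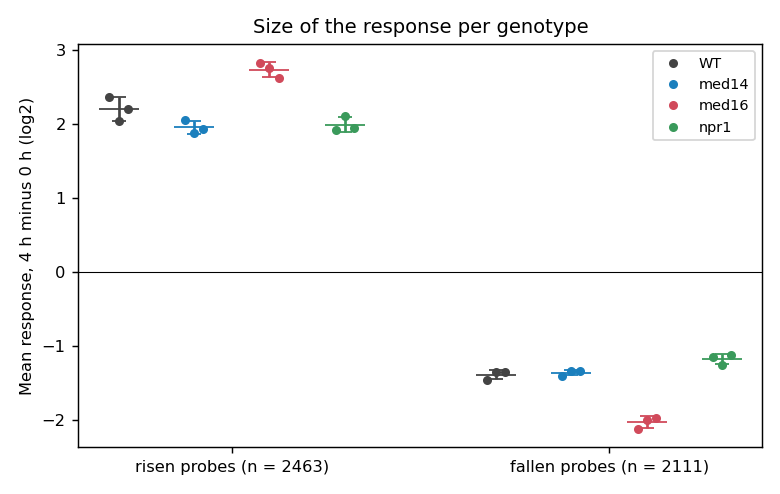
Mean response (4 h minus 0 h, log2) of the 2463 risen and the 2111 fallen probes in each genotype, with 1 point per replicate number and bars for the mean ± SD of the 3. The med16 points lie farthest from 0 in both sets.

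Across all probes the response of npr1 followed that of WT most closely, with a correlation of 0.952 over probes, against 0.897 for med16 and 0.826 for med14. Probes are not independent replicates, so no p is given. Of the 14144 probes that responded in WT, 80.2% were also called in the same direction in npr1, 83.2% in med16 and 72.7% in med14. Probes called in opposite directions numbered 15 for npr1, 419 for med16 and 460 for med14.

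**Figure D3:**
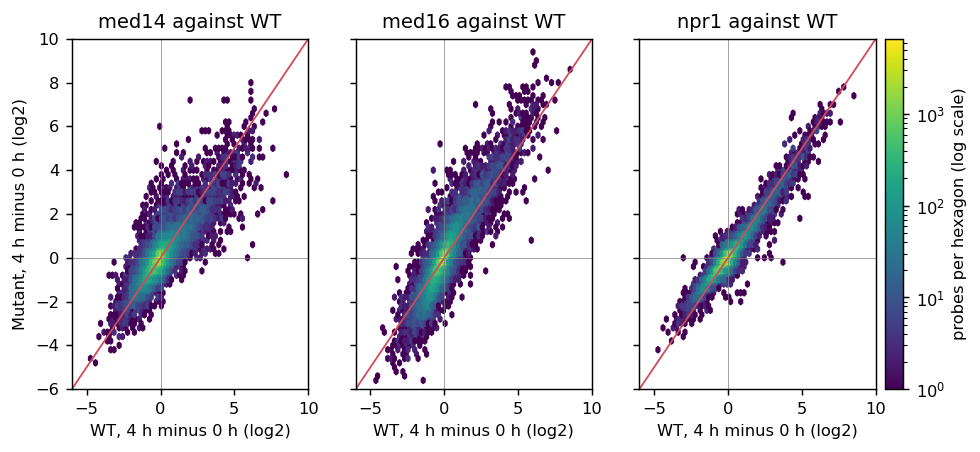
Response (4 h minus 0 h, log2) of each mutant on the vertical axis against that of WT on the horizontal axis for all 33143 probes, with colour for the number of probes per hexagon on a log scale and a diagonal line for equal responses. The probes scatter least in npr1 (r = 0.952 over probes) and most in med14 (r = 0.826), and in med16 they tilt to larger responses.

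The comparison of med14 with WT at 0 h asked what the mutation changed before the response. A_84_P549811 was higher by 4.14 ± 0.445 (SE, n = 3 per group; adjusted p = 1.75e-06, limma) and A_84_P11480 by 3.64 ± 0.247 (adjusted p = 1.05e-08, limma). A_84_P50100 was lower, at 9.31 ± 0.222 (SD) in med14 and 13.98 ± 0.0972 in WT, a difference of -4.67 ± 0.308 (adjusted p = 7.53e-09, limma), and A_84_P22571 was lower with a difference of -4.14 ± 0.199 (adjusted p = 1.26e-10, limma). In total 4356 probes were higher and 3666 lower in med14. At least 2-fold the majority turned, with 317 higher and 612 lower. With spike-in scaling 1072 were higher and 1795 lower, so that the share of higher probes was 37.4% in place of 54.3%. Without replicate 2 in all groups 5247 probes were called.

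In med16 at 0 h, 4443 probes were higher and 3615 lower than in WT, but at least 2-fold 192 were higher and 478 lower. A_84_P192434 was at 13.49 ± 0.0908 (SD, n = 3) in med16 and 8.50 ± 0.349 in WT, a difference of 4.97 ± 0.126 (SE; adjusted p = 4.43e-15, limma). A_84_P564098 was higher by 3.32 ± 0.424 (adjusted p = 7.73e-06, limma). A_84_P255680 was lower with a difference of -4.92 ± 0.178 (adjusted p = 1.09e-12, limma), and A_84_P50100, low in med14 as well, with -4.83 ± 0.230 (adjusted p = 3.82e-11, limma). Spike-in scaling left 402 higher and 927 lower probes, 30.2% higher in place of 55.1%, and without the array block 4926 probes were called.

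The npr1 samples at 0 h differed from WT at 343 probes, 255 higher and 88 lower, and at least 2-fold 29 higher and 13 lower. A_84_P11480 was higher by 3.93 ± 0.249 (SE, n = 3 per group; adjusted p = 7.03e-08, limma) and A_84_P850803 by 2.53 ± 0.252 (adjusted p = 2.92e-05, limma). For A_84_P850803 the WT mean of 6.51 ± 0.0631 (SD) lay among the background limits of these samples (6.48 to 6.64), so the size is uncertain. A_84_P277560 was lower with a difference of -2.30 ± 0.138 (adjusted p = 5.84e-08, limma). A_84_P796276 was not above background in npr1 and was at least 7.51-fold higher in WT, where it was at 9.51 ± 0.534 (SD; adjusted p = 3.61e-05, limma). The count rested on single samples: it was 125 without replicate 1 of npr1 and 136 without replicate 2 of WT. It was 54 with spike-in scaling and 13 when the 6 samples were fitted alone.

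At 4 h, 5479 probes were higher and 4553 lower in med14 than in WT, but at least 2-fold 740 were higher and 1087 lower. A_84_P186914 was at 13.83 ± 0.135 (SD, n = 3) in med14 and 8.76 ± 0.906 in WT, a difference of 5.07 ± 0.692 (SE; adjusted p = 1.37e-05, limma), and A_84_P549811, already higher at 0 h, was higher by 4.38 ± 0.445 (adjusted p = 4.53e-07, limma). A_84_P18821 was lower with a difference of -6.38 ± 0.274 (adjusted p = 1.21e-11, limma) and A_84_P69204 with -5.39 ± 0.227 (adjusted p = 9.71e-12, limma). The med14 mean of A_84_P18821 (6.505 ± 0.0338, SD) lay under the background limits of its samples (6.508 to 6.535), so the size is uncertain. With spike-in scaling 1383 were higher and 3590 lower, 27.8% higher in place of 54.6%, and the median difference of all probes moved from 0.01 to -0.15.

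In med16 at 4 h, 6878 probes were higher and 6177 lower than in WT, but at least 2-fold 684 were higher and 988 lower. A_84_P186914 was higher by 5.56 ± 0.516 (SE, n = 3 per group; adjusted p = 5.08e-08, limma) and A_84_P15207 by 3.99 ± 0.223 (adjusted p = 6.18e-11, limma). A_84_P18821 was lower with a difference of -5.77 ± 0.205 (adjusted p = 3.55e-13, limma), and A_84_P12921 with -5.01 ± 0.173 (adjusted p = 2.64e-13, limma). The probe with the largest excess and the one with the largest deficit among those named were thus the same in both Mediator mutants. With spike-in scaling 1209 were higher and 3193 lower, 27.5% higher in place of 52.7%, and the median difference moved from 0.01 to -0.11.

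In npr1 at 4 h, 555 probes were higher and 559 lower than in WT, and at least 2-fold 43 were higher and 88 lower. A_84_P11480 and A_84_P850803, the probes with the largest excess at 0 h, remained higher, by 3.12 ± 0.249 (SE, n = 3 per group; adjusted p = 2.24e-06, limma) and 2.54 ± 0.252 (adjusted p = 1.54e-05, limma). The WT mean of A_84_P850803 was near background at 4 h as well (6.49 ± 0.0865, SD, with limits of 6.42 to 6.65). A_84_P125601 was at 10.83 ± 1.35 (SD) in npr1 and 15.85 ± 0.357 in WT, a difference of -5.13 ± 0.631 (adjusted p = 0.000157, limma) that was no longer called without replicate 3 in all groups. A_84_P812910 was lower with a difference of -4.72 ± 0.424 (adjusted p = 5.88e-06, limma). The total of 1114 fell to 374, 453 and 560 without replicate 1 of npr1, replicate 1 of WT and replicate 3 of npr1. It was 156 when the 6 samples were fitted alone, and 58 higher and 97 lower with spike-in scaling (37.4% higher in place of 49.8%).

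The difference between responses asked which probes responded otherwise in a mutant than in WT. In med14 such a difference was called at 5266 probes, 2589 higher and 2677 lower, and at least 2-fold 802 higher and 743 lower. A_84_P129226 changed in med14 from 7.63 ± 0.139 (SD, n = 3) to 13.72 ± 0.188, while WT had 9.41 ± 0.157 at 0 h and 9.35 ± 0.0419 at 4 h, which gives a difference of 6.14 ± 0.160 (SE; adjusted p = 2.09e-14, limma). A_84_P186914 differed by 5.08 ± 0.979 (adjusted p = 0.00115, limma), a call lost without replicate 2 in all groups. A_84_P18821 rose from 7.00 ± 0.358 to 12.88 ± 0.922 in WT but was not above background in med14 at 0 h and was at 6.51 ± 0.0338 at 4 h, so that the size of this called difference (adjusted p = 3.21e-08, limma) is not measured. A_84_P21916 differed by -5.65 ± 0.491 (adjusted p = 3.9e-07, limma). Its size is uncertain, as the WT mean at 0 h (6.59 ± 0.291, SD) lay among the background limits (6.48 to 6.64). The spread in med14 at 0 h was wide (6.99 ± 0.843). With spike-in scaling 722 were higher and 1076 lower, 40.2% higher in place of 49.2%, and calls numbered 2815 and 3001 without replicate 1 or replicate 3 of all groups.

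The response of med16 differed from that of WT at 11144 probes, 5463 higher and 5681 lower, and at least 2-fold 971 higher and 1084 lower. A_84_P831354 differed by 5.38 ± 0.608 (SE, n = 3 per group; adjusted p = 1.13e-06, limma), with a wide spread in WT at 0 h (11.40 ± 1.57, SD). A_84_P186914 differed by 4.90 ± 0.719 (adjusted p = 2.31e-05, limma), with a wide spread in med16 at 0 h (7.34 ± 1.88, SD). A_84_P18821 differed by -5.14 ± 0.285 (adjusted p = 3.01e-10, limma) and A_84_P16974 with -4.08 ± 0.343 (adjusted p = 3.32e-08, limma). For A_84_P18821 the med16 mean at 0 h (6.45 ± 0.217, SD) lay under the background limits of its samples (6.55 to 6.69), so the size is uncertain. With spike-in scaling 836 were higher and 1636 lower, 33.8% higher in place of 49.0%.

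In npr1 98 probes passed, 40 higher and 58 lower (at least 2-fold 12 and 22), against 3304 at an unadjusted p under 0.05. A_84_P563250 rose in WT from 6.39 ± 0.258 (SD, n = 3) to 10.05 ± 1.02 and was not above background in npr1 at 4 h. The difference between responses (adjusted p = 0.00311, limma) is -3.56 with npr1 at 4 h at the background limit. This is no firm bound, as the npr1 mean at 0 h (6.41 ± 0.320, SD) also lay under the limits of its samples (6.43 to 6.69). A_84_P822840 differed by -2.99 ± 0.410 (SE; adjusted p = 0.00437, limma) and A_84_P18312 by 1.35 ± 0.270 (adjusted p = 0.0427, limma). A_84_P796276 fell by 2.27 ± 0.311 in WT (adjusted p = 5.1e-06, limma) and was not above background in npr1 at either time, so its called difference (adjusted p = 0.0451, limma) has no measured size. These calls rested on few samples: leaving out replicate 1 of npr1 at 0 h left 10 probes, and each single sample but replicate 2 of WT at 4 h and of npr1 at 4 h reduced the count to 63 or fewer. The 12 samples of both genotypes fitted alone called 2, and spike-in scaling left 9, all lower.

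**Figure D4:**
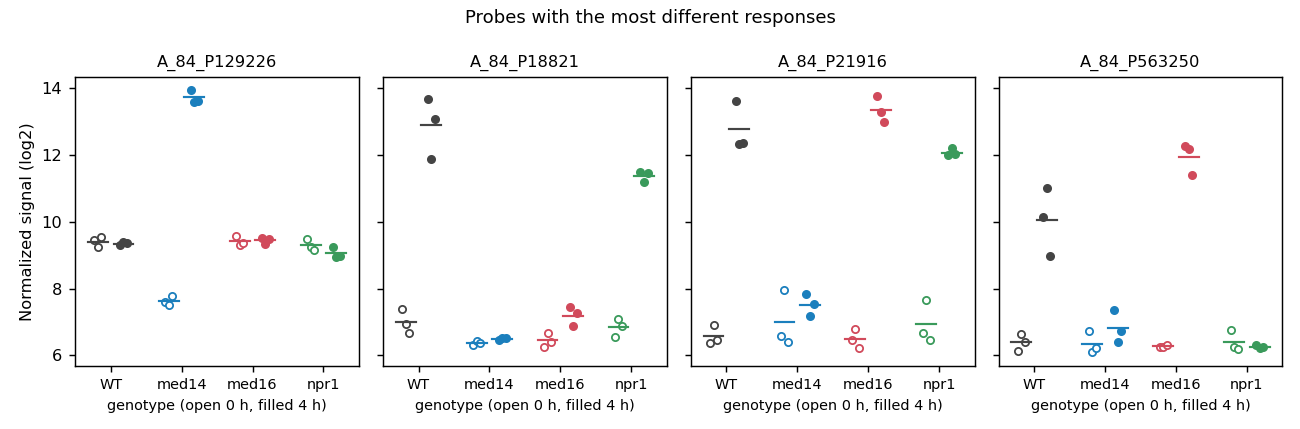
Normalized signal (log2) of 4 probes with large differences between responses, by genotype, with open circles for the 3 samples of 0 h, filled circles for the 3 of 4 h and short lines for group means. A_84_P129226 rises from 7.63 to 13.72 in med14 alone among the 4 genotypes drawn, and A_84_P18821 has a mean of 6.51 in med14 and 7.19 in med16 at 4 h, against 12.88 in WT.

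The responses of both Mediator mutants were compared directly. They differed at 6986 probes, where med14 had the higher value at 3793 and the lower at 3193, but at least 2-fold the higher at 829 and the lower at 971. A_84_P129226 differed by 6.06 ± 0.160 (SE, n = 3 per group; adjusted p = 2.64e-14, limma) and A_84_P192434 by 3.33 ± 0.239 (adjusted p = 1.23e-07, limma). A_84_P21916 was at 13.35 ± 0.395 (SD) in med16 and 7.52 ± 0.328 in med14 at 4 h, a difference between responses of -6.32 ± 0.491 (adjusted p = 1.98e-07, limma). Its med16 mean at 0 h (6.49 ± 0.287, SD) lay under the background limits of its samples (6.55 to 6.69). In med14 at 0 h it was at 6.99 ± 0.843, a wide spread, so the size is uncertain. A_84_P563250 was also called (adjusted p = 1.35e-06, limma), but was not above background at 0 h in either mutant, so the size of the difference is not measured. At 4 h it was at 6.83 ± 0.490 (SD) in med14 and 11.95 ± 0.471 in med16. Among risen probes 1424 had a smaller response in med14 than in med16 and 52 a larger one, and among fallen probes 1382 had a smaller and 22 a larger one. Spike-in scaling left 956 higher and 1089 lower, which also turned the majority, and leaving out replicate 1 or replicate 3 of all groups left 4286 and 4130.

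The effects of the Mediator mutations on the response were also set against each other. Counted by sign, the difference from the WT response was positive in both at 1686 probes and negative in both at 1611. Independent lists of the same sizes would share 427 and 459. The signs were opposite at 343 probes (885 for independent lists). A negative difference can be a smaller rise or a larger fall, and a positive one a larger rise or a smaller fall. A_84_P18821 and A_84_P186914 were among the shared probes. The correlation of both differences over probes was 0.512, against 0.367 in simulations of unchanged groups that share the WT samples, and the covariance was 0.131 against 0.0116. The 3 WT samples per time cannot be divided into parts of at least 2, so part of the excess may come from the shared WT samples. At least 2-fold in both, 433 probes were higher and 200 lower. With spike-in scaling the med14 difference alone was called at 722 higher and 1076 lower probes, so the shared 1686 and 1611 would not hold there. Whether the scale or the spread of the spike-in levels removed the calls was not tested. Without replicate 1 of all groups 915 were shared as higher and 835 as lower, and without replicate 3 these were 1039 and 889.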

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

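The tests of dye, overall scale, batch, shared WT samples and exchanges within arrays, and the reading of the spike-ins one by one, were chosen only after the result was seen.

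The responses of the genotypes differed by the test of the difference itself at 5266 probes for med14 against WT, 11144 for med16 against WT, 98 for npr1 against WT and 6986 for med14 against med16. The probe furthest apart was A_84_P129226 for med14 against WT (6.14, log2) and A_84_P831354 for med16 against WT (5.38). For npr1 against WT it was A_84_P563250 (-3.56 with npr1 at 4 h at the background limit, which is no firm bound). For med14 against med16 it was A_84_P21916 (-6.32, an uncertain size, as its med16 mean at 0 h lay under the background limits). Groups of 3 samples were too small for a test of outlying samples.

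The counts were set against 100 splits of the 6 samples of each time into groups of 3, the real one included. As many calls came from 3 splits for med14 against med16, 5 for med14 against WT and 6 for npr1 against WT. All of these lay within 1 exchange of the real split or of the split with all labels exchanged at 4 h. Their number depends on how many such near splits were among the 100, so these counts do not decide on chance. For med16 against WT as many calls came from 2 splits, but these splits break up the arrays that WT and med16 samples share. Of the 32 exchanges within arrays 2 gave as many calls, the real one and the exchange of all 3 arrays at 4 h (11674). Where genotypes differ at both times these 2 are expected, and 2 of 32 is a share of 0.0625, so this count cannot decide. The 18 exchanges more than 1 array away from both called 0 probes. The highest other splits called 11601 (med14), 11674 (med16), 1495 (npr1) and 10309 (med14 against med16), several times the real count for npr1. In each case this split exchanged all 3 labels of both genotypes at 4 h and none at 0 h, which turns the term into the sum of the genotype differences at both times and points to the genotypes as a structure of the samples. Of the 100 splits, those more than 1 exchange away from this one and from the real one called at most 3, 1, 2 and 3 probes.

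For comparisons of 3 samples with 3, the 10 splits are too few for a share under 0.05, and in each comparison 1 split, the real one, reached the real count. The highest other split called 0 probes for WT, 16 for med14, 0 for med16 and 0 for npr1 in 4 h against 0 h (real counts 14144, 14534, 16639 and 13006). At 0 h it called 0 for med14, 6 for med16 and 1 for npr1 against WT (8022, 8058 and 343), and at 4 h 1, 1 and 0 (10032, 13055 and 1114).

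The larger response in med16, upward and downward, was weighed against technical explanations. A dye bias in the size of the response would change sign with the dye arrangement. The excess over WT was at least 0.427 (log2) in both probe sets and all 3 replicate numbers. A dye bias equal at both times cancels here, since each genotype carried the same dye at 0 h and 4 h within a replicate number. A different overall scale would move risen and fallen probes one way, yet after spike-in scaling the median difference was -0.754 over the same 2111 fallen probes and 0.44 over the same 2463 risen ones. A stretched signal range in med16 at 4 h would widen the spread of the spike-ins. The ratio of this spread to that of WT at 4 h was 0.963, itself with a spread of 0.0357. It was set against 1.27, the ratio of the median risen responses, but a stretch acts on signal levels and not on responses. All columns had also been normalized to nearly one distribution beforehand, so this test does not decide. As a hypothesis, the loss of MED16 may enlarge the combined response to bacteria, infiltration and time of day, whose parts, and whose timing, were not tested.

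The 10 spike-in controls, outside the probes compared, were lower at 4 h by -0.242 (log2), in 10 of 10 controls (6 arrays per time, exact permutation p = 0.00216, the smallest that 924 splits give). A displacement in rank by the normalization would move them like probes of like signal, which moved by -0.230 on average. The mean shift beyond those probes was -0.0126, but it averages 6 controls below them and 4 above (from -0.136 to 0.155, SD 0.130), so it does not decide, and this explanation stays open. A batch of labelling or hybridization cannot be told apart from time, since 0 arrays held samples of both times. A change in the messenger share of total RNA was not tested.

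At 4 h, 583 probes differed from WT in opposite directions in med16 and npr1, where independent lists would share 219. The npr1 list behind this count held 1114 probes and fell to 374 without replicate 1 of npr1 at 4 h, so the 583 would not hold there. Shared WT samples would make the correlation of both differences positive (0.379 in simulations), and it was -0.141. Of the 583 probes, 98.1% lay beyond WT in med16 in the direction of the mean response, against 72.8% of all probes called in med16. A larger response in med16 together with a smaller one in npr1 may therefore account for the opposition, as a hypothesis found and tested on the same data.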

How the results depend on the processing

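Spike-in scaling, alone or without probes below the median signal, and the choice of probes from genotypes not compared were added after the results were seen; all other settings were planned. The spike-in levels varied within groups with SDs of 0.0416 to 0.266 (log2), against median probe SDs of 0.0940 to 0.122. How far this spread, and not the scale, removed calls under spike-in scaling was not tested. No named probe changed direction in the settings run for it. Some named calls were lost outside the leave-one-out settings: 4 with the compared groups fitted alone and 2 without the dye term. Another 2 were lost with trend and robust, 2 with spike-in scaling and 1 without the array block. Spike-in scaling turned the majority of calls from falls to rises in the 4 responses (WT from 38.5% to 69.2% up) and from higher to lower in both Mediator mutants against WT at both times (med14 at 0 h from 54.3% to 37.4% higher) and in med14 against med16 (54.3% to 46.7%). The planned threshold of 2-fold turned it the same way in these comparisons (WT 54.1%, med14 55.8% and npr1 60.5% up, med14 and med16 34.1% and 28.7% higher at 0 h and 40.5% and 40.9% at 4 h, med14 against med16 46.1%) except in the med16 response (47.6% up), and also in the med14 minus WT response (49.2% to 51.9%). The cause of the changes below was not tested, except that a fold threshold lowers a count by construction. Repeated quantile normalization, median centring and leaving out the dimmest 25% of probes kept the counts of the 14 comparisons within 1.5 times. So did the array as a fixed block for the 3 comparisons of med16 with WT, and leaving out the npr1 samples at 0 h for the 11 comparisons without them. Without the dye term npr1 minus WT responses gave 63 calls, with trend and robust 39. Without the array block med16 at 0 h gave 4926. Fitted alone, npr1 gave 13 (0 h), 156 (4 h) and 2 (response). Samples of one replicate number on other arrays were more alike (r over 0.1 in 30 of 72 pairs, median 0.077) than those of other numbers and groups (12 of 168, median -0.057). The main model did not take the numbers to pair the samples, so a batch that follows them is not excluded. With the replicate block npr1 gave 577, 1713 and 161, and no other count moved by over 1.5 times.

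With at least 2-fold, the responses gave 4296 (WT), 4230 (med14), 7092 (med16) and 3352 (npr1), the mutants in that order 929, 670 and 42 at 0 h, 1827, 1672 and 131 at 4 h, the differences of response 1545, 2055 and 34, med14 against med16 1800, and the overlaps 433 and 200. Without the fold threshold the differences in response size were -0.023 (med14) and 0.32 (med16) for risen and -0.19 (med16) and 0.076 (npr1) for fallen probes. Spike-in scaling gave 9090 (med14) and 7128 (npr1) for the responses, 2867, 1329 and 54 at 0 h, 4973, 4402 and 155 at 4 h, 1798, 2472 and 9 for the differences of response, 2045 for med14 against med16, and response sizes of -0.11 (med14, from 0.00) and -0.87 (med16, from -0.67) for fallen probes chosen again after scaling. Without probes below the median signal as well, the responses gave 8052 (WT, 63.1% up), 8070 (med14, 58.3%), 10921 (med16, 53.2%) and 6536 (npr1, 61.0%).

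Over all settings without a replicate, npr1 ranged from 65 to 366 (0 h), 115 to 1609 (4 h) and 6 to 124 (response), med14 from 5247 to 7305 (0 h) and 2815 to 5542 (response), med14 against med16 from 4130 to 6987, and the overlaps from 915 to 1131 and 835 to 1154. Where these leave 2 samples of a group, the spread is pooled over groups, and without replicate 1 dye could not be separated from genotype. Among named probes, the npr1 responses of A_84_P796276 and A_84_P18312 were lost in 13 of 15 such settings each, A_84_P822840 in 3, A_84_P563250 in 1. Combining probes of a gene and testing gene lists were not run, as the probes carry no gene names. Only 60.4% to 75.3% of probes per sample were above background, which limits the rest.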

Other observations

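The probes in this part were picked from those already named and the overlaps with npr1 were examined only after the results were seen.

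Some probes separated med14 and npr1 from WT and med16 at both times. The arrays were divided in the same way, each holding WT with med16 or med14 with npr1, and the SEs include the variation between arrays. Whether these sets of arrays differed in another way was not tested. A_84_P11480 was higher than in WT by 3.64 ± 0.247 (SE, n = 3 per group; adjusted p = 1.05e-08, limma) in med14 and by 3.93 ± 0.249 in npr1 at 0 h, and by 2.80 ± 0.247 and 3.12 ± 0.249 at 4 h. In med16 it differed by 0.04 ± 0.184 (adjusted p = 0.941, limma) at 0 h and by -0.51 ± 0.184 at 4 h. A_84_P277560 was lower with a difference of -2.01 ± 0.137 in med14 and of -2.30 ± 0.138 in npr1 at 0 h, and of -2.27 ± 0.137 and -2.38 ± 0.138 at 4 h, with 0.01 ± 0.102 (adjusted p = 0.988, limma) and 0.14 ± 0.102 in med16. At 4 h A_84_P812910 was lower with a difference of -3.97 ± 0.420 in med14 and of -4.72 ± 0.424 in npr1, and higher by 1.03 ± 0.314 (adjusted p = 0.0123, limma) in med16.

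Over all probes at 0 h, med14 and npr1 were both higher than WT at 195 probes and both lower at 64, where independent lists would share 33.5 and 9.73. The correlation of both differences was 0.536, against 0.723 in simulated unchanged groups, which share the WT samples and their own arrays. The covariance was 0.0454 against 0.0157 in the simulations. For med16 and npr1 at 0 h 165 probes were both higher and 51 both lower (34.2 and 9.60 for independent lists), and 37 went opposite ways (39.6). Their correlation was 0.284, against 0.382 in the simulations (lowest 0.369), and the covariance 0.0200 against 0.00618. Real differences particular to a single mutant lower a correlation, so neither correlation shows less sharing than in unchanged groups. The simulations of unchanged groups gave 0 shared calls for either pair. They held no real differences and thus few calls to share, so this 0 does not show how much shared WT samples add. With 3 WT samples per time the shared WT samples could not be divided, so a part of these overlaps that comes from them is not excluded. Both overlaps also rest on the npr1 list of 343 probes at 0 h, which fell to 125 without replicate 1 of npr1 at 0 h.

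Other probes separated both Mediator mutants from WT and npr1. At 0 h A_84_P50100 was lower than in WT with a difference of -4.67 ± 0.308 in med14 and -4.83 ± 0.230 in med16, and at 4 h of -4.11 ± 0.308 and -4.30 ± 0.230. In npr1 it differed by -0.88 ± 0.311 (adjusted p = 0.215, limma) at 0 h and 0.01 ± 0.311 at 4 h. A_84_P186914 responded by 7.11 ± 0.692 in med14 and 6.92 ± 0.692 in med16, against 2.03 ± 0.692 in WT and 2.54 ± 0.692 in npr1. Over all probes at 0 h both were higher than WT at 2247 and both lower at 1899 (584 and 400 for independent lists). The correlation was 0.624, against 0.361 in simulations of unchanged groups that share the WT samples, and the covariance 0.0824 against 0.00581. A part that comes from the shared WT samples is not excluded here either. The shared counts would also not hold with spike-in scaling, which left 402 higher and 927 lower probes in med16 at 0 h.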
